A study of Homo sapiens with 12 samples.

How the data were processed

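Omni-ATAC libraries were made from 50000 cells each of the human cholangiocyte line H69 and sequenced with paired reads of 51 bp, per the labels' protocols. The 12 libraries form 4 groups of 3: DMSO with vehicle, DMSO with TGF beta, CPTH6 with vehicle and CPTH6 with TGF beta. Groups and replicate numbers came from the sample titles.

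The deposited files are 1 list of peaks per library, called separately for each library with MACS2, per the file headers. The coordinates are hg38, per the submitters' processing notes, which also name BWA, Picard, bedtools and DiffBind with no role or version. Filters, duplicate removal and any shift of reads for the transposase are not given in the sources used here. Each peak carries a score deposited by the authors, whose unit no header names. The lowest score of each list lies between 2.00 and 2.12, and the scores were used only to rank or filter peaks within a list. Per the file headers, replicate 1 of each group ran on flow-cell lane 2 and replicates 2 and 3 on lane 3, so lane is balanced over groups. The lists hold neither reads nor depths, so the depth of each library is unknown, no counting interval can be given, and a missing peak means only that no peak was called. Lists held between 10530 and 30728 peaks. Peaks outside chromosomes 1 to 22 and X were left out (between 51 and 66 per list).

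Peaks of all 12 lists were merged with bedtools 2.31.1 into 49068 regions where they overlapped by at least 1 bp, and a library counted as having a region where 1 of its peaks overlapped it by at least 1 bp. 7857 regions had a peak in all 12 libraries and 13342 in 1. Equal lists kept the strongest 10479 peaks of each library, the length of the shortest list, and gave 21439 regions. A region was gained where 3 of 3 treated and 0 of 3 reference libraries had it, and lost in the reverse case; over both backgrounds the rule was at least 5 of 6 against at most 1 of 6. The score percentile of a gained or lost region is its rank by score within a list, averaged over the 3 libraries of the group that holds it in that comparison. Libraries outside the comparison do not enter, so 1 region can have different percentiles in different comparisons. For regions present in all 12 libraries the average is over all 12.

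Genes came from a RefSeq gene table of assembly GRCh38.p14, the same build as hg38, with 19974 protein-coding genes. The table used here gives neither strand nor exons, and no genome sequence was used. Some planned steps were therefore changed: peaks were assigned to the nearest protein-coding gene by distance from the peak midpoint to the gene body (within 100 kb) in place of the nearest start site, and the promoter share became the share of peaks whose midpoint was within 1 kb of either annotated end of a gene. The planned motif comparisons were not run. Between 92.6% and 93.4% of peaks per library had a gene within 100 kb.

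The 16 gene lists, with 484 genes, were fixed before the data were examined: TGF beta pathway and early targets, extracellular matrix, epithelial to mesenchymal transition, cholangiocyte identity, hepatocyte, fibroblast and stellate, endothelial and leukocyte markers, AP-1 factors, senescence and secreted factors, histone acetylation, autophagy and lysosome, stress and apoptosis, proliferation, ribosomal proteins, and cytoskeleton and focal adhesion. Genes named in the text are list genes with a gained or lost region (at most 20 per comparison, by number of regions and then score percentile), the 5 gained and 5 lost regions of highest score percentile per comparison, and 11 genes fixed beforehand (SMAD7, CCN2, FN1, TGFBI, SKIL, KRT7, KRT19, SOX9, KAT2A and KAT2B, and 1 that is not reported here). Members of a list beyond these are named only as parts of that list's count. The rule was fixed beforehand, and the genes it takes follow from the data. 3 more genes (PTPRE, DLC1 and PKP1) lie outside the lists and the rule, and were chosen after their values were seen.

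Values per library were compared with exact permutation tests, two-sided, with labels exchanged within DMSO and within CPTH6 for TGF beta, and within vehicle and within TGF beta for CPTH6 (400 arrangements, smallest p 0.005). 3 libraries against 3 give 20 arrangements and no p under 0.1. Differences between TGF beta effects were tested by permuting the residuals of the additive model (400 arrangements), a test that is approximate and not exact. Gained or lost regions were compared with lists and gene ends by Fisher's exact test, with regions present in at least 3 of the 6 libraries as background. Adjustment was by Benjamini-Hochberg. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

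The procedures were tested on simulated data. With 200 regions planted in each direction among 49068, the rule for TGF beta in DMSO recovered 71% of gained and 73% of lost regions, with 0 in the wrong direction. The rule over both backgrounds recovered 93.5% and 95%. Planted regions were set to be present in nearly all libraries with TGF beta and nearly none with vehicle, or the reverse. These recoveries follow from that setting, so they test the procedure and say nothing of weaker changes or of false calls. For peaks per gene, counts were simulated with equal list lengths in all libraries, and changed genes were taken only above a minimum mean number of peaks. There 91% of genes changed by 3-fold had an unadjusted p under 0.05, against 1.51% of unchanged genes, and 0 changed genes passed adjustment among 15533. Real list lengths differ, so these rates are not those of the test on the real lists. A count of 0 genes past adjustment therefore reflects what this test can reach. For values per library, in 2000 simulations without an effect the stratified test called 4.45% and the test of a difference between effects 6.25%, so the latter is slightly liberal. Simulated values had the same spread in all groups. Real spreads differ (SD of peak number 2018 in DMSO with vehicle and 6640 in CPTH6 with vehicle), so these rates need not hold for the real values.

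Alternatives were a stricter score threshold, equal lists, other overlap and merging rules, other windows, a replicate block, and leaving out each library. Lane 3 alone, the nearest gene end, equal lists for the gene lists of gained and lost regions and for the splits by genes, an adjustment of the gene-end share for list length, the regions used as background for the overlap of gained sets, and changes to the choice and lists of held-out regions were added after the data were seen.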

Results

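Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts open chromatin, in H69 cells. H69 is an immortalised line of human cholangiocytes, the epithelial cells that line the bile ducts. Cells received DMSO or 50 uM CPTH6, an inhibitor of the histone acetyltransferases KAT2A and KAT2B that the labels call an inhibitor of H3K9 acetylation. Each was combined with vehicle or 10 ng per ml TGF beta, a cytokine that drives matrix production, for 16 h. The 4 groups held 3 libraries each. The design asks which regions TGF beta opened or closed, and whether CPTH6 altered that response. Each library had its own deposited list of peaks, with between 10479 and 30665 peaks on chromosomes 1 to 22 and X. Read totals were not used here, so the depth behind each list is unknown. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The passage ranges in the labels start at 30 and end at 32 in replicate 1 and at 35 to 38 in replicate 3, where the end differs by group. Passage was not used. A region was called gained where 3 of 3 treated and 0 of 3 reference libraries had a peak, and lost in the reverse case. Because list length sets how many regions can be called, the numbers of gained and lost regions are given for all peaks and for the strongest 10479 peaks of every library (equal lists). Lists of equal length pull gains and losses toward balance by construction. Named regions and members of gene lists come from all peaks unless stated. Distances to genes are from the midpoint of a region, and a region is called inside a gene where its midpoint is.

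In DMSO, 954 regions were gained and 879 lost with TGF beta. The gained regions included 3 outside TGFBI, which encodes a matrix protein induced by TGF beta, and 2 outside TNC, which encodes the matrix glycoprotein tenascin C. Pairs of gained regions also lay inside TNS1 and inside TNS3, which encode tensins of focal adhesions. Regions lost included 2 beside KRT19, a keratin that marks cholangiocytes. Of the 25 extracellular matrix genes with a measured region, 9 had a gained region and 1, the collagen gene COL4A2, also had a lost one.

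The TGFBI regions lay on chromosome 5 at 135993951 to 135994208, 136006786 to 136007135 and 136016979 to 136017443 (hg38). They stood 34908, 22027 and 11777 bp from the nearer end of the gene. The region farthest from the gene had a peak in 0 of 3 libraries of CPTH6 with TGF beta, the middle one in 2 of 3 and the nearest in 3 of 3. The TNC regions lay on chromosome 9 at 115008597 to 115008856 and 115213762 to 115214147. The stronger TNS1 region, at 217934301 to 217934754 on chromosome 2, had a mean score percentile of 88.8 over the 3 DMSO libraries with TGF beta. Of the TNS1 regions gained with TGF beta in CPTH6, the stronger had 38.1 over the 3 CPTH6 libraries with TGF beta. These percentiles rank peaks within the lists of different libraries, so they do not measure a change in accessibility at TNS1. A region at 117206926 to 117207105 on chromosome 11, inside TAGLN (the smooth muscle protein transgelin) and 449 bp from a gene end, was also gained. The lost KRT19 regions lay on chromosome 17 at 41528303 to 41528536 and 41539094 to 41539356, with midpoints 112 and 10917 bp from the gene, and the first overlapped the end of the gene. With equal lists TNS1, TNS3 and TAGLN had a gained region and TNS3 also a lost one, whereas TGFBI, TNC and KRT19 had neither a gained nor a lost one.

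**Figure D1:**
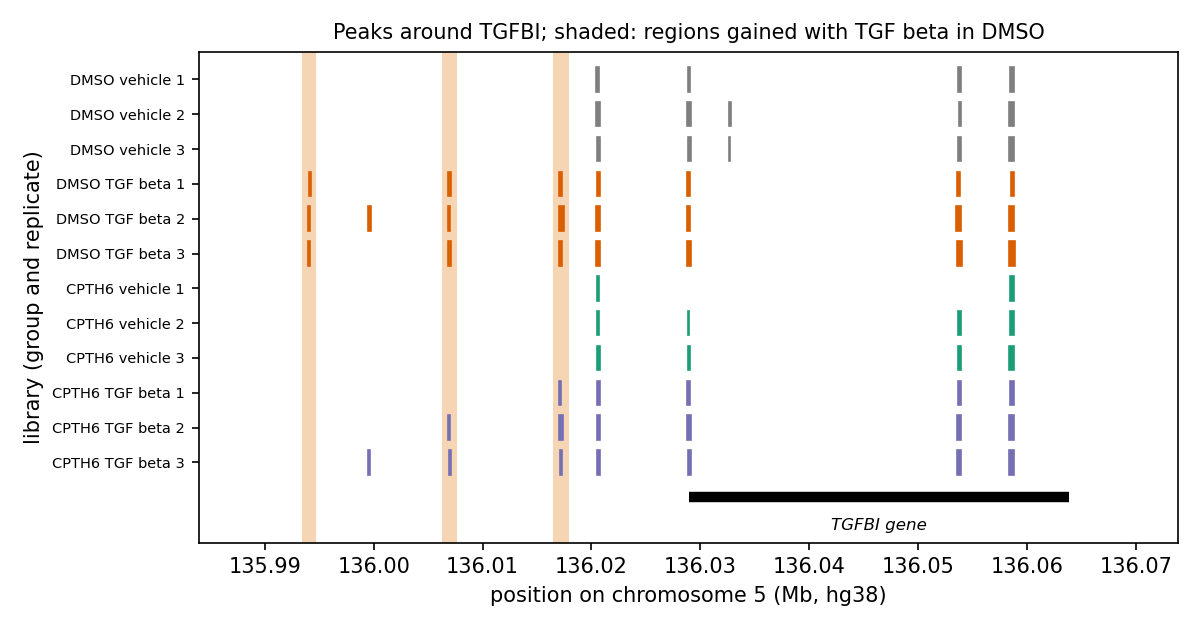
Peaks of each library (rows, by group and replicate) along chromosome 5 around TGFBI (x axis, position in Mb, hg38). Shaded bands mark the 3 regions with a peak in 3 of 3 DMSO libraries with TGF beta and in 0 of 3 with vehicle, and the black bar marks the gene.

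By score, the strongest gained region lay inside SPOCK1, which encodes a testican proteoglycan, on chromosome 5 at 137470382 to 137471110 (percentile 95.7). The next 4 lay 5972 bp from PRKAR1B, 84072 bp from TLN2 (the adhesion protein talin 2), inside CRTC1 and inside SUGCT, with percentiles from 94.5 down to 92.5. All of these gained regions had a peak in 3 of 3 libraries of CPTH6 with TGF beta. In CPTH6 with vehicle the SPOCK1 and SUGCT regions had one in 2 of 3, CRTC1 in 1, and PRKAR1B and TLN2 in 0. The strongest lost region, on chromosome 5 at 173719610 to 173720057 (percentile 89.0), was 103184 bp from the nearest protein-coding gene. It was followed by regions inside PPP1R16B (82.3), PTPN9 (79.8) and TBC1D2B (78.2), and one 19538 bp from CAPZB (76.8). Gene tables without strand or exons were used, so introns, exons and start sites are not distinguished.

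Among the gene lists, extracellular matrix genes held 10 of the 954 gained regions against 81 of 26172 regions present in at least 3 of the 6 libraries (odds ratio 3.75, two-sided Fisher's exact test, adjusted p = 0.0114 over 16 lists). With equal lists the odds ratio was 6.36 (Fisher's exact test, adjusted p = 0.0385). Against regions present in exactly 3 of the 6 libraries it was 3.57 and the call was lost (Fisher's exact test, adjusted p = 0.0753). Of 10 splits of the 6 DMSO libraries, 2 gave an odds ratio as large as 3.75 (highest other 8.75). Regions are not replicates, so these tests compare sets of regions and do not set the enrichment apart from a chance split of libraries. The members with a gained region were ADAM12, COL1A2, COL4A2, COL7A1, COL8A1, FN1, LAMA3, TNC and VCAN, which encode collagens, fibronectin, a laminin chain, other matrix proteins and a metalloprotease. The other 15 lists did not pass among gained regions, nor did any of the 16 among lost ones (Fisher's exact test; 2 lists at an unadjusted p under 0.05). TGF beta pathway genes held 9 gained and 5 lost regions, among them regions assigned to RUNX1 in both directions. BHLHE40, CDKN1A, CDKN2B, LTBP4 and SMAD6 each had a gained region, and LTBP1, LTBP2, LTBP3 and TGFB2 a lost one. Cholangiocyte identity genes held 2 gained and 7 lost regions (adjusted p = 0.174 for lost, Fisher's exact test), the lost ones including regions assigned to EHF, GATA6, KRT8, KRT19 and NOTCH2. Epithelial to mesenchymal transition genes held 4 gained and 6 lost regions (adjusted p = 0.174 for lost, Fisher's exact test), with SNAI2, TWIST2 and ZEB2 among the genes with a lost region. Cytoskeleton and focal adhesion genes held 8 gained and 4 lost regions. Senescence and secreted factor genes held 4 and 2, stress and apoptosis genes 3 and 1, AP-1 factors 0 and 3, ribosomal protein genes 0 and 2, and proliferation genes 0 and 0. Among markers of cells other than cholangiocytes, fibroblast and stellate markers held 3 gained regions, assigned to COL1A2, DPT and THY1 (odds ratio 2.74), hepatocyte markers 2 (4.07, and 1 lost region), leukocyte markers 2 (5.30) and endothelial markers 1 (1.15). None of these 4 passed (Fisher's exact test, smallest adjusted p = 0.439). Histone acetylation genes held 2 gained regions, assigned to KAT2B and NCOA3, and autophagy and lysosome genes 2, assigned to ATG5 and RB1CC1. With equal lists the members with a gained and with a lost region numbered 5 and 0 for the TGF beta pathway, 3 and 0 for matrix genes (ADAM12, COL4A2 and COL7A1) and 3 and 1 for epithelial to mesenchymal transition. They numbered 1 and 3 for cholangiocyte identity, where GATA6 had the gained region, 3 and 2 for the cytoskeleton list and 0 and 2 for histone acetylation, where KAT2B had a lost region.

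Gained regions lay away from gene ends, and lost ones did so less. Only 3.77% of them (36 of 954) were within 1 kb of an annotated gene end, against 18.3% of lost regions (161 of 879; odds ratio 0.175, 95% interval 0.117 to 0.256, two-sided Fisher's exact test, p = 8.73e-25) and 39.4% of the background. With equal lists, 475 regions were gained and 305 lost, with 5.05% and 33.1% near a gene end, against 52.2% of the background. Regions are not replicates, so this p compares 2 sets of regions and not the treatments. The other splits of the 6 libraries gave at most 463 regions in 1 direction with all peaks and 100 with equal lists. With 10 splits the share of splits as large cannot be under 0.1.

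**Figure D2:**
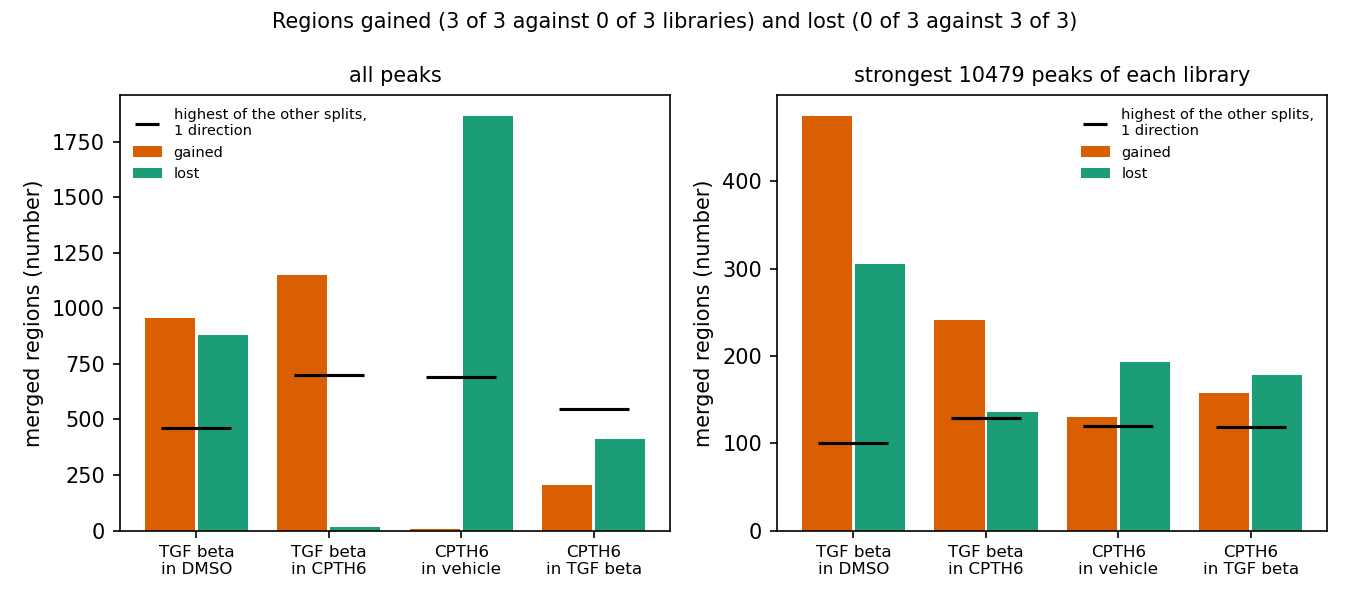
Number of merged regions (y axis) gained and lost in the 4 comparisons (x axis), with all peaks on the left and the strongest 10479 peaks of each library on the right; the y scales differ. Black lines give the highest count in 1 direction among the other splits of the same 6 libraries; with CPTH6 in vehicle the lost regions fall from 1866 to 193 while the gained ones rise from 7 to 130.

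In CPTH6, 1148 regions were gained and 14 lost with TGF beta. Gained regions included 2 inside LTBP1, which encodes a protein that binds latent TGF beta, 2 inside TNS1, 2 inside MYH9 (non-muscle myosin) and 2 outside AMOTL2. Single gained regions lay inside SMAD3, a signal transducer of TGF beta, across an end of TGFB1, which encodes the cytokine (midpoint 5 bp outside), 11777 bp from TGFBI and 92706 bp from FN1, which encodes fibronectin. Another was that of COL7A1, an anchoring collagen. The COL7A1 region lay on chromosome 3 at 48595479 to 48596100, 461 bp from a gene end. The TGFBI region was the one nearest to the gene that was also gained in DMSO.

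With equal lists the counts in CPTH6 were 241 gained and 136 lost, so gains were 98.8% of the calls with all peaks and 63.9% with equal lists. The LTBP1 regions lay on chromosome 2 at 33212194 to 33212444 and 33210687 to 33210907. They had peaks in 2 and 1 of 3 libraries of DMSO with vehicle. The strongest gained regions lay 91043 bp from MRPL14 on chromosome 6 at 44022094 to 44022722 (percentile 91.4), inside GARNL3, inside C12orf42, 12067 bp from LOC124904930 and inside ZBTB38 (an additional 4 with percentiles from 89.0 down to 83.7). In DMSO with vehicle they had peaks in 2, 3, 2, 1 and 3 of 3 libraries, in that order, so each was also called in a library with neither TGF beta nor CPTH6. The lost regions of highest score that had a gene within 100 kb were near VMP1, SLC5A6 and LIPC; the VMP1 region, on chromosome 17 at 59846382 to 59846805, was absent from all 6 TGF beta libraries and present in all 6 vehicle libraries. Of 35 TGF beta pathway genes with a measured region, 9 had a gained region, as did 6 of 23 matrix genes and 8 of 32 cytoskeleton genes. With equal lists these were 2 of 30, 0 of 15 and 1 of 25. None of the 16 lists passed among gained regions (smallest adjusted p = 0.724, Fisher's exact test; 0 lists at an unadjusted p under 0.05). With equal lists, 18.7% of gained and 43.4% of lost regions were within 1 kb of a gene end (odds ratio 0.301, two-sided Fisher's exact test, p = 6.19e-07). With all peaks the order was the reverse, with 17.5% of gained regions and 0 of the 14 lost ones (Fisher's exact test, p = 0.146). With all peaks, other splits of these 6 libraries gave up to 701 regions in 1 direction.

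Over both backgrounds, a region counted as gained where at least 5 of 6 TGF beta and at most 1 of 6 vehicle libraries had a peak. There were 808 gained and 101 lost regions, or 312 and 152 with equal lists, so gains were 88.9% and 67.2% of the calls. Matrix genes held 7 of the 808 gained regions and did not pass here (odds ratio 3.29, Fisher's exact test, adjusted p = 0.130; with equal lists odds ratio 3.44, adjusted p = 0.682). Peaks per gene were compared for 15533 genes with an exact permutation test stratified by DMSO or CPTH6 (two-sided, smallest possible p = 0.005). 0 genes passed Benjamini-Hochberg adjustment (permutation test, smallest adjusted p = 1). By the same permutation test 427 genes had an unadjusted p under 0.05, 409 of them with more peaks under TGF beta, and adjusted over the list alone 0 of the 430 list genes passed (smallest adjusted p = 0.358). With equal lists, 222 genes had an unadjusted p under 0.05 (permutation test), 145 with more peaks. The share of peaks assigned to each gene list, with equal lists, gave 0 of 16 lists past adjustment for TGF beta (exact permutation test, smallest adjusted p = 0.34, with 1 list at an unadjusted p under 0.05). For CPTH6 it also gave 0 of 16 (exact permutation test, smallest adjusted p = 0.576, with 1 list at an unadjusted p under 0.05).

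TNC, TGFBI, LTBP1, TNS1 and COL7A1 were among the list genes at the smallest p, which is not past adjustment. TNC had 1.0 ± 1.0 peaks in DMSO with vehicle, 5.67 ± 1.53 in DMSO with TGF beta, 0.333 ± 0.577 in CPTH6 with vehicle and 3.67 ± 1.15 in CPTH6 with TGF beta (mean ± SD, n = 3; exact permutation p = 0.005). TGFBI had 5.67 ± 0.577, 8.33 ± 0.577, 4.33 ± 1.15 and 7.0 ± 1.0 peaks in the same order. LTBP1 had 8.67 ± 0.577, 11.3 ± 1.53, 4.67 ± 3.51 and 9.67 ± 1.15. With equal lists the TNC means were 0.333, 0.667, 0 and 0.333, the TGFBI means were 4.0, 5.0, 4.0 and 4.0, and the LTBP1 means were 3.33, 4.33, 2.67 and 4.67.

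Genes fixed for report showed these values (peaks per gene, n = 3) in the same order. SMAD7, an inhibitory SMAD, had means of 6.33, 6.67, 4.0 and 6.0, and SKIL, a SMAD corepressor, 1.33, 2.0, 1.67 and 1.67. CCN2, which encodes connective tissue growth factor, had 5.33, 3.33, 2.67 and 4.0, and FN1 2.33, 3.0, 0.667 and 2.0. The cholangiocyte genes KRT7, KRT19 and SOX9 had 6.33, 3.67 and 4.67 peaks in DMSO with vehicle and 5.33, 1.0 and 3.0 in DMSO with TGF beta. They had 3.0, 0 and 2.33 in CPTH6 with vehicle and 5.67, 1.0 and 3.67 in CPTH6 with TGF beta. KAT2A had means of 0.667, 0, 0 and 0.333 and KAT2B 4.0, 3.33, 3.33 and 4.67. For TGF beta, none of these genes except TGFBI had an unadjusted p under 0.05.

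The share of peaks near a gene end was lower with TGF beta in each background. Among the strongest 10479 peaks it was 54.2% ± 1.96 in DMSO with vehicle and 48.3% ± 0.799 in DMSO with TGF beta (SD, n = 3). It was 53.3% ± 1.46 in CPTH6 with vehicle and 49.9% ± 0.641 in CPTH6 with TGF beta (SD, n = 3). The stratified difference was -4.66 percentage points (exact permutation test, two-sided, p = 0.005, the smallest it can give). Within flow-cell lane 3 alone, which held replicates 2 and 3, it was -4.59 points (exact permutation p = 0.0556, the smallest possible there), and lane 2 held 1 library per group. With all peaks it was -4.44 points (exact permutation p = 0.025), and -2.31 points after adjustment for list length. The adjusted value had a permutation p of 0.005, but its slope was fitted within the real groups and not refitted, so that test is not exact. The unadjusted all-peak difference came mainly from the CPTH6 background, with -7.23 points (exact permutation p = 0.1) against -1.65 points in DMSO (exact permutation p = 0.4). The CPTH6 difference was 0.364 points (exact permutation p = 0.675), but 4.40 points when all peaks were used (exact permutation p = 0.03). With all peaks, the replicate block lost the call (exact permutation p = 0.0625), and lane 3 gave 3.51 points (exact permutation p = 0.0556, the smallest possible there). The difference between the TGF beta effects in DMSO and CPTH6 was -2.58 points with equal lists (residual permutation p = 0.115), but 5.58 points with all peaks (residual permutation p = 0.11).

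**Figure D3:**
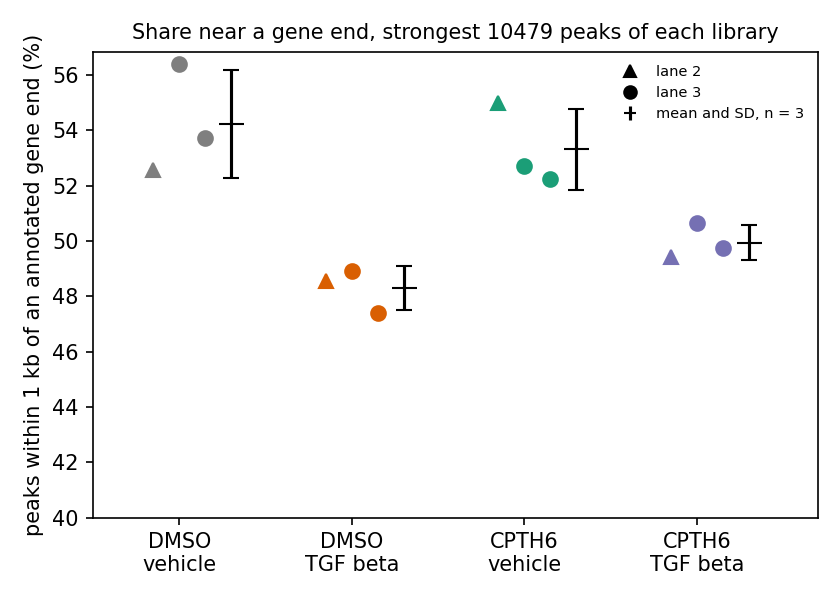
Percent of the strongest 10479 peaks of each library whose midpoint was within 1 kb of an annotated gene end (y axis, from 40%), by group (x axis); triangles are lane 2, circles lane 3, and bars give the mean and SD of 3 libraries. The 6 TGF beta libraries lie between 47.4% and 50.7%, below the 6 vehicle libraries.

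With vehicle, 1866 regions were lost and 7 gained with CPTH6. Lost regions included 3 beside KRT19, 2 inside SMAD3 and 1 at 1274 bp from it, 2 assigned to COL8A1 and 2 near ACTB, which encodes cytoplasmic actin. Single lost regions lay 9506 bp from ANKRD1, a target of mechanical and YAP signalling, and 20570 bp from the collagen gene COL1A1. With equal lists, 193 regions were lost and 130 gained, so gains were 0.374% of the calls with all peaks and 40.2% with equal lists. The CPTH6 vehicle group had the lowest mean list length of the 4 groups.

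The strongest lost regions lay 54608 bp from HIVEP2 on chromosome 6 at 142696738 to 142696983 (percentile 82.5), inside PPP1R16B, inside C8orf74, inside ROPN1L and inside KLF13. In CPTH6 with TGF beta they had peaks in 3, 1, 3, 0 and 3 of 3 libraries, in that order. The HIVEP2, C8orf74 and KLF13 regions were thus present under CPTH6 and missing only from the group with the shortest lists. The PPP1R16B region was also among those lost with TGF beta in DMSO, a comparison that shares the DMSO vehicle libraries. The strongest gained region lay 19055 bp from ACSL1 on chromosome 4 at 184845473 to 184845825 (percentile 58.8), and another lay 1277 bp from STC2, which encodes stanniocalcin 2. The SMAD3 regions lay on chromosome 15 at 67147055 to 67147286, 67175011 to 67175292 and 67064189 to 67064467. Members of 15 lists had lost regions: 6 each of the TGF beta pathway, matrix, epithelial to mesenchymal transition, cholangiocyte and cytoskeleton lists, and 5 each of the fibroblast, senescence and histone acetylation lists. The histone acetylation genes were CREBBP, HDAC5, HDAC7, HDAC11 and YEATS2. With equal lists 0 members of the TGF beta pathway, epithelial to mesenchymal transition, cytoskeleton, senescence and histone acetylation lists had a lost region, and 1 each of the matrix (COL1A1), cholangiocyte and fibroblast lists did. SMAD3 then had a gained region and no lost one. None of the 16 lists passed (smallest adjusted p = 0.386, Fisher's exact test, with 1 list, hepatocyte markers, at an unadjusted p under 0.05). With equal lists, 22.3% of gained and 44.6% of lost regions were within 1 kb of a gene end (odds ratio 0.358, two-sided Fisher's exact test, p = 5.07e-05).

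With TGF beta present, 206 regions were gained and 410 lost with CPTH6. Lost regions included the TAGLN region and the farthest of the TGFBI regions described above, each with a peak in 3 of 3 libraries of DMSO with TGF beta and in 0 of 3 of every other group. Single lost regions lay across an end of TGFB1I1 (a focal adhesion protein; midpoint 114 bp outside), 34761 bp from ITGB1 (an integrin), inside ATG7 (an autophagy enzyme) and inside CREBBP (a histone acetyltransferase). Gained regions lay 31364 bp from the AP-1 gene JUN and inside ZEB1, each present in 3 of 3 libraries of DMSO with vehicle.

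The JUN region lay on chromosome 1 at 58815230 to 58815591 and the ZEB1 region on chromosome 10 at 31319272 to 31319690. The strongest lost regions lay 80708 bp from AZIN1 on chromosome 8 at 102745365 to 102745823 (percentile 83.9), 54012 bp from MDGA1, inside KLHL6, inside IGF1R (the insulin-like growth factor receptor) and 10428 bp from HORMAD2. The strongest gained regions with a gene within 100 kb lay inside GABRR2, 4062 bp from ARHGEF2 and 540 bp from GSTA4. Of 37 TGF beta pathway genes with a measured region, 5 had a lost region (LTBP4, RUNX1, SMAD6, TGFB1I1 and TGFBI) and 0 a gained one. With equal lists none of these 5 did, and 2 others of 30, KLF10 and SKI, had a lost region. None of the 16 lists passed (0 lists at an unadjusted p under 0.05, Fisher's exact test). Gained regions were nearer to gene ends than lost ones, with 24.3% against 10.2% within 1 kb (odds ratio 2.80, two-sided Fisher's exact test, p = 7.63e-06). With equal lists, 157 regions were gained and 178 lost, so gains were 33.4% of the calls with all peaks and 46.9% with equal lists. With all peaks, another split of these 6 libraries gave 545 regions in 1 direction, more than the 410 lost.

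Peaks per gene gave 0 genes past adjustment for CPTH6 (exact permutation test stratified by treatment, smallest adjusted p = 1). By that permutation test 553 genes had an unadjusted p under 0.05, 550 with fewer peaks, and with equal lists 86 did, 37 with more and 49 with fewer. Adjusted over the list alone, 0 of 430 genes passed (exact permutation test, smallest adjusted p = 0.5375, with 31 at an unadjusted p under 0.05). At the smallest p, COL1A1 had 4.67 ± 0.577 peaks in DMSO with vehicle and 2.0 ± 0 in CPTH6 with vehicle, and 5.0 ± 0 and 3.33 ± 1.15 in DMSO and CPTH6 with TGF beta (n = 3, exact permutation p = 0.005). LTBP4 had 3.67 ± 2.08, 0.667 ± 0.577, 4.67 ± 0.577 and 2.33 ± 0.577 in that order. With equal lists the COL1A1 means were 1.67, 1.0, 1.67 and 0.333. The LTBP4 means were then 0.667, 0, 0.333 and 1.33, so with TGF beta LTBP4 had more peaks in CPTH6 than in DMSO.

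The number of peaks was 29131 ± 2018 in DMSO with vehicle, 27162 ± 4177 in DMSO with TGF beta, 17557 ± 6640 in CPTH6 with vehicle and 25922 ± 2382 in CPTH6 with TGF beta (SD, n = 3). The stratified CPTH6 difference was -6407 peaks (exact permutation test, two-sided, p = 0.045). Within lane 3 it was -6163 (exact permutation p = 0.111, where 0.0556 is the smallest possible). It was no longer past 0.05 in 9 of the 12 tests that each left out 1 library, and without CPTH6 vehicle replicate 1, which had 10479 peaks, it was -4638 (exact permutation p = 0.08). The TGF beta difference was 3198.5 peaks (exact permutation p = 0.31; 2215 in lane 3, exact permutation p = 0.389). The TGF beta effect in DMSO minus that in CPTH6 was -10334 peaks (residual permutation p = 0.05, not under the threshold).

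**Figure D4:**
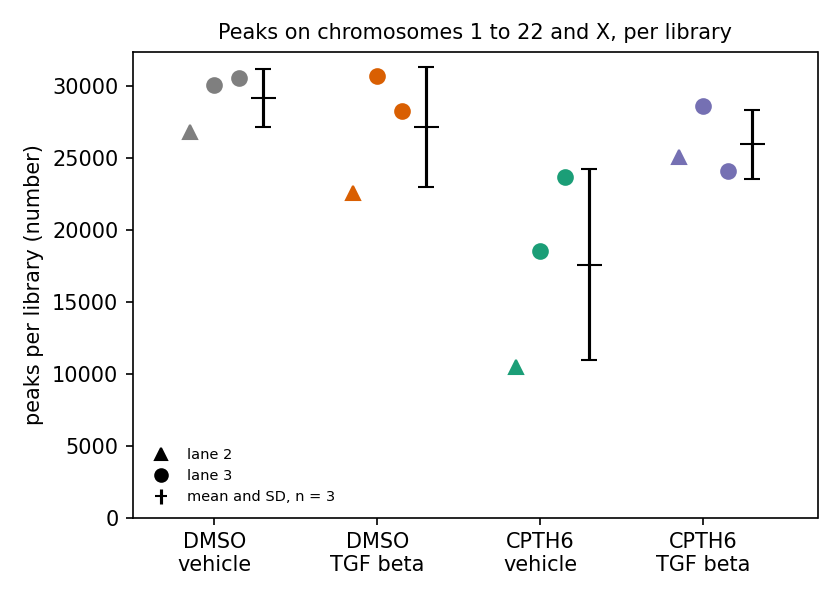
Number of peaks per library on chromosomes 1 to 22 and X (y axis), by group (x axis); triangles are lane 2, circles lane 3, and bars give the mean and SD of 3 libraries. The 3 libraries of CPTH6 with vehicle, between 10479 and 23648 peaks, lie below the 3 of DMSO with vehicle, between 26817 and 30527.

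To compare the TGF beta response between DMSO and CPTH6, regions gained in DMSO were chosen with 1 library of each DMSO group held out, in 9 choices, and their occupancy was read in the libraries not used. With equal lists, 63.5% ± 1.78 of the regions had a peak in a held-out DMSO library with TGF beta and 20.3% ± 2.73 in one with vehicle (SD, n = 3). In CPTH6 the values were 51.5% ± 0.799 with TGF beta and 27.0% ± 3.05 with vehicle (SD, n = 3; exact permutation p = 0.1, the smallest 3 against 3 can give). The difference was 43.2 points in DMSO and 24.5 points in CPTH6, or 49.3 and 37.3 with all peaks. With all peaks and without DMSO TGF beta replicate 1, 2 or 3, which loosens the choice of regions, they were 29.4 and 20.6, 25.1 and 24.0, and 25.3 and 22.9. For regions chosen in CPTH6 instead, the difference was 20.9 points in CPTH6 and 19.8 points in DMSO with equal lists, but 36.1 and 10.6 points with all peaks. For regions lost in DMSO it was -26.2 points in DMSO and -9.06 points in CPTH6 with equal lists. With all peaks it was -33.7 points in DMSO, but in CPTH6 the occupancy was higher with TGF beta (30.7%) than with vehicle (19.7%; exact permutation p = 0.4). With both choices of gained regions weighing equally, the DMSO difference exceeded the CPTH6 one by 8.82 points with equal lists, and with all peaks it was 6.74 points smaller.

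**Figure D5:**
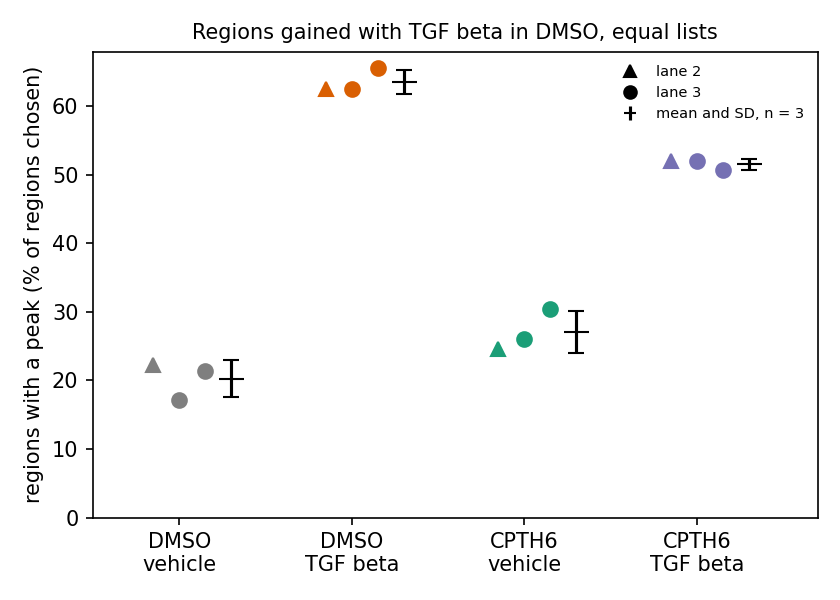
Percent of regions gained with TGF beta in DMSO that had a peak in each library (y axis), by group (x axis), from the strongest 10479 peaks per library; DMSO libraries were held out of the choice of regions. Triangles are lane 2, circles lane 3, and bars give the mean and SD of 3 libraries; the CPTH6 libraries with TGF beta lie between 50.6% and 52.1%, below the DMSO libraries with TGF beta.

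The gained sets of the DMSO and CPTH6 comparisons, which share no library, had 169 regions in common, against 67.5 for independent sets drawn from the 16223 regions present in 3 to 9 of the 12 libraries, as any called region is. With equal lists they shared 40 against 14.1. The lost sets shared 2 against 0.759, or 11 against 5.12 with equal lists. Of the 954 regions gained in DMSO, 278 (29.1%) had a peak in 3 of 3 libraries of CPTH6 with TGF beta and 231 (24.2%) in 0 of 3. The TAGLN region was among the latter, and the GADD45B region, 6528 bp from that stress gene on chromosome 19 at 2469375 to 2469823, among the former.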

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

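The tests chosen only after the result was seen were those of list length and lane for the CPTH6 vehicle losses, of list length for the share of all peaks, with regions chosen in CPTH6, without CPTH6 vehicle replicate 1, of splits for genes with equal lists, of list length in the splits for genes, and the counts of splits for the 4 comparisons of 3 against 3 libraries.

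With CPTH6 in vehicle, gains were 0.374% of the called regions, and with lists of equal length 40.2%. Equal lengths pull gains and losses toward balance whatever made the lists shorter, so this value cannot tell whether list length or CPTH6 caused the excess of losses. Lane is argued against as the source of the shorter lists, since within lane 3 the CPTH6 vehicle lists averaged 0.696 of the DMSO vehicle lists in length, the longest holding 23648 peaks and the shortest of DMSO 30049. Read totals found in the lists numbered 0, so lower read depth and an effect of CPTH6 on accessibility cannot be told apart.

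Regions gained with TGF beta lay near gene ends less often than lost ones in DMSO and, with equal lists only, in CPTH6, and gained regions being weaker peaks is argued against, since in DMSO with equal lists their median score percentile was the higher one (43.2 against 34.2). With regions in 4 bins of score percentile the Mantel-Haenszel odds ratio was 0.130 (95% interval 0.0800 to 0.212), but the gap was not seen in the bin of highest score, where 2.53% of 158 gained and 2.70% of 37 lost regions were near a gene end. List length is argued against as the whole cause for the share at equal list length. There the TGF beta difference was -4.66 points (exact permutation p = 0.005, the smallest possible), or -4.41 after a further adjustment that had little left to remove. For the share of all peaks, adjustment took the difference from -4.44 to -2.31 points, so there list length as a part of the cause stays open. Both adjusted values had a permutation p of 0.005. Their slopes were fitted within the real groups and not refitted for each arrangement, so these tests are not exact and may favour the real grouping. For regions gained or lost over both backgrounds the gap was -29.4 points, and 17 of 100 splits gave a gap as large (largest -40.7, from 260 regions against 464), so chance cannot be excluded for that gap. Lost regions also lay near gene ends less often than the background (33.1% against 52.2%), CPTH6 in vehicle gave such a gap without TGF beta (22.3% against 44.6% with equal lists), so the gap was not particular to TGF beta, and no biological explanation was tested.

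The TGF beta difference in occupancy was smaller in CPTH6 than in DMSO for regions chosen in DMSO. With equal lists, the choice of regions is argued against as the whole cause: with regions chosen in DMSO and in CPTH6 weighing equally, the differences were 31.5 and 22.7 points, the excess was 8.82, and 2 of 100 exchanges of DMSO and CPTH6 labels gave as large an excess (highest other 9.97), but with all peaks the direction turned (-6.74 points, with 36.7 in CPTH6, and 68 of 100 exchanges as large). For regions chosen in DMSO, CPTH6 vehicle replicate 1 is argued against, since the excess was 18.7 points with it and 19.9 without it at the same list length (43.2 against 23.3). Without it and with lists of 18543 peaks the excess was 22.5 points (48.6 against 26.2). The equally weighed excess was not computed without it. For equal lists chance is argued against, since DMSO had 403 more gained and lost regions than CPTH6, and 1 of 100 exchanges, the real one, gave as many (highest other 337). Exchanged groups mix DMSO and CPTH6 libraries, so any effect of CPTH6 lowers their counts. The exchanges therefore cannot tell a changed TGF beta response from another effect of CPTH6. With all peaks, leaving out DMSO TGF beta replicate 2 brought the differences for regions chosen in DMSO to 25.1 and 24.0 points. CPTH6 vehicle libraries agreed least with each other (mean Jaccard index 0.546, against 0.619 in DMSO with vehicle), so noisier lists, unequal depth and a weaker response under CPTH6 stay open, and the direction depends on list length.

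The TGF beta effect in DMSO minus that in CPTH6 was -3.70 Mb for covered length (residual permutation p = 0.025, adjusted p = 0.05). It was -26.7 bp for median peak width (residual permutation p = 0.025, adjusted p = 0.05). It was -2.91 percentage points for the share of peaks inside a gene with equal lists (residual permutation p = 0.02, adjusted p = 0.05).

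For 3 against 3 libraries the 10 splits are too few for a share under 0.05, and 1 of 10, the real one, gave as many regions in each comparison. The real total and the highest other were 1833 and 498 for TGF beta in DMSO, 1162 and 705 for TGF beta in CPTH6, 1873 and 698 for CPTH6 in vehicle, and 616 and 589 for CPTH6 in TGF beta. With equal lists they were 780 and 183, 377 and 204, 323 and 195, and 335 and 208. Over both backgrounds chance is argued against, with 1 of 100 splits, the real one, as large for all peaks (909, highest other 595) and for equal lists (464, highest other 289). For peaks per gene, 3 of 100 splits, the real one included, gave as many genes at an unadjusted p under 0.05 as TGF beta (427, highest other 488, permutation test). For CPTH6, 4 of 100 gave as many (553, highest other 1191). Both shares are just under 0.05 and unadjusted, so with all peaks chance is not excluded. Each of these highest splits was also the one of the 100 with the largest difference in mean list length, 5702 peaks (488 genes) and 8431 peaks (1191 genes), against 3198.5 and 6407 for the real groups, so with all peaks the gene counts may reflect list length. A larger difference than in the real groups was found in 27 splits for TGF beta and in 3 for CPTH6. For TGF beta this argues against list length as the whole cause, since only 3 of 100 splits gave as many genes. With equal lists 1 of 100 splits, the real one, gave as many genes for TGF beta (222, highest other 116, permutation test) and for CPTH6 (86, highest other 65). For the extracellular matrix list in DMSO, 2 of 10 splits gave an odds ratio as large (3.75, highest other 8.75), and the splits are too few for a share under 0.05.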

How the results depend on the processing

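Tests within lane 3, with the nearest gene end, with regions chosen in CPTH6, and without CPTH6 vehicle replicate 1 at equal list length were chosen only after the result was seen. So were equal lists for the gene lists of gained and lost regions and for the splits by genes. The adjustment of the gene-end share for list length and the background for the overlap of gained sets were also added then. The other alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. Of the alternative values, 218 kept their side of the threshold or stayed close to the main value, 76 moved, 14 lost a call and 6 gained one. Some of the 218 could hardly change: held-out occupancy can give no p under 0.1 (exact permutation test), and peaks per gene can scarcely pass adjustment. The 218 are therefore not a measure of stability. Depth is unknown, so what it limits could not be measured. The planned motif comparisons were not run, since no genome sequence was used.

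The CPTH6 difference in peak number lost its call as covered length (-1894270 bp, exact permutation p = 0.065), with the replicate block (-6407, exact permutation p = 0.0938) and in lane 3 (-6163, exact permutation p = 0.111). Left out singly, libraries gave -7930 to -4638, and the call was kept only without DMSO TGF beta replicate 1, CPTH6 TGF beta replicate 2 or CPTH6 vehicle replicate 3. The difference between TGF beta effects gained a call at a stricter threshold (-7558, residual permutation p = 0.02) and as covered length (-3696340 bp, residual permutation p = 0.025). These p-values are unadjusted, and for covered length the adjusted residual permutation p was 0.05, not under the threshold. The difference between TGF beta effects on peak number ranged from -13380 to -6796 with libraries left out, and 3 of 12 gained a call. The TGF beta difference ranged from 1429 to 4721. The cause was not tested. Presence of regions showed no sign of pairing by replicate number. Deviations from group means correlated by -0.0254 to 0.0286 in same-numbered libraries and by -0.0269 to 0.0267 in others. Replicate 1 of each group shared a lane, and such correlations cannot exclude a batch shared by replicate number. The replicate block gave 1505 gained and 220 lost regions over both backgrounds, under a rule of its own.

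At the stricter score threshold (8.37) 443 regions were gained with TGF beta in DMSO, 4 lost with TGF beta in CPTH6, 3 gained with CPTH6 in vehicle, 132 gained and 224 lost with CPTH6 in TGF beta, and 473 gained and 35 lost with TGF beta over both. Equal lists gave 475 gained and 305 lost with TGF beta in DMSO, 241 and 136 with TGF beta in CPTH6, 130 and 193 with CPTH6 in vehicle, 178 lost with CPTH6 in TGF beta, and 312 and 152 with TGF beta over both; fewer peaks enter by construction.

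With fewer libraries the rule asks for fewer, so counts rise by construction. Lane 3 gave 2259 gained and 2124 lost with TGF beta in DMSO, 2127 and 350 with TGF beta in CPTH6, 224 and 3635 with CPTH6 in vehicle, 712 and 1805 with CPTH6 in TGF beta, and 2371 and 1058 with TGF beta over both. Lane 3 with equal lists gave 1608 gained with TGF beta in DMSO, 737 lost with TGF beta in CPTH6, 750 and 971 with CPTH6 in vehicle, 854 and 965 with CPTH6 in TGF beta, and 1554 and 1253 with TGF beta over both. Libraries left out singly gave 1105 to 1945 gained and 1041 to 1846 lost with TGF beta in DMSO, 1221 to 2935 and 29 to 210 with TGF beta in CPTH6, 16 to 156 and 1973 to 4236 with CPTH6 in vehicle, 275 to 587 and 560 to 1307 with CPTH6 in TGF beta, and 826 to 1229 and 112 to 419 with TGF beta over both.

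The TGF beta difference in gene-end share was -3.70 points in lane 3 with the list length set anew (exact permutation p = 0.0556, the smallest possible there), and -5.07 to -3.33 with libraries left out. The CPTH6 difference was 4.40 points with all peaks (exact permutation p = 0.03), a call lost with the replicate block (exact permutation p = 0.0625). With equal lists it was -0.0517 to 1.18 with libraries left out. Against regions in exactly 3 of 6 libraries, 0 lists passed among regions gained with TGF beta in DMSO (Fisher's exact test, matrix odds ratio 3.57, adjusted p = 0.0753). The held-out occupancy difference in CPTH6 ranged from 20.6 to 41.9 points with all peaks and libraries left out.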

Other observations

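The genes in this paragraph lie outside the gene lists and were chosen after their values were seen, among those at the smallest p of the permutation test, and none passed adjustment (adjusted p = 1). PTPRE, which encodes a receptor tyrosine phosphatase, had 5.0 peaks in DMSO with vehicle and 8.67 with TGF beta, and 4.67 and 9.0 in CPTH6 (mean, n = 3, exact permutation p = 0.005). DLC1 had 7.67 and 10.7 in DMSO and 5.0 and 9.67 in CPTH6. PKP1, which encodes the desmosomal protein plakophilin 1, had 2.67 and 7.0 in DMSO and 1.67 and 4.67 in CPTH6.

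Among the strongest 10479 peaks, the mean Jaccard index was 0.581 over the 12 pairs of libraries of the same group, with means of 0.619 in DMSO with vehicle, 0.582 in DMSO with TGF beta, 0.546 in CPTH6 with vehicle and 0.578 in CPTH6 with TGF beta. The libraries of CPTH6 with vehicle agreed more with those of DMSO with vehicle (0.563 over 9 pairs) than with each other. It was 0.562 over the 18 pairs that differed only in CPTH6, 0.539 over the 18 that differed only in TGF beta and 0.534 over the 18 that differed in both. Pairs share libraries, so these values were not tested. Regions present in all 12 libraries had a median score percentile of 77.0, against 42.9 for regions gained and 34.7 for regions lost with TGF beta in DMSO. Each list also held between 8 and 10 mitochondrial peaks, which were left out.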
